A study of Mus musculus with 12 samples.

How the data were processed

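Poly-A RNA-seq libraries were made from 12 samples of mouse cells, 2 replicates of each of 6 populations. The populations were embryonic fibroblasts (MEF), 4 populations sorted by flow cytometry on days 3 and 6 of reprogramming, and induced pluripotent stem cells (iPSC). The kit named for the libraries is a directional one. The tools named for read processing are STAR 2.3.0, Picard 1.100 and HTSeq 0.6.0 with genome build mm9, with no further parameters, and the gene annotation is not given in the sources used here. The authors deposited 1 table of counts per sample, with whole numbers of reads per Ensembl gene identifier. The counting ignored strand, so a gene and a partner on the opposite strand that share exonic sequence cannot be told apart in these values. Each table held 37583 genes and 5 summary lines for reads outside genes, ambiguous, low-quality, unaligned or multiply aligned reads. The summary lines were used to describe the libraries and in 2 of the alternatives.

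Gene symbols, biotypes, exon lengths, chromosomes and overlaps came from the GENCODE M21 annotation, which is on a later genome build, so no coordinates are printed. A symbol was found for 32860 of the 37583 identifiers (87.4%), and identifiers without one stayed in the tests. Of 727 entries in the fixed gene lists, 2 were matched by a synonym and 8 were not matched: Sox1, Rhox5, Psmb9, Rian, Mirg, Snrpn, Kcnq1ot1 and Flg. Of the genes that the report names by the rule below, exons of Adh7, Atp12a, B4galnt3, Bnip3, Cacna2d2, Cdkn1c, Dlk2, Edn1, Esrp1, H19, Igfbp7, Krt7, Lama3, Mogat2, Myb, Ndufa4l2, Olig1, Pcsk1n, Penk, Pfkp, Plch2, Pou5f1, Prss12, Slc2a1, Sox21, Stac, Sv2b, Tmem54, Trim9 and Vcam1 overlap those of a gene on the opposite strand.

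Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr on the 6 groups, which left 16240, and libraries were scaled by TMM. All 12 libraries entered 1 quasi-likelihood negative binomial fit with a mean per group and robust dispersion estimates, which had 6 residual degrees of freedom, a prior of 5.05 degrees of freedom and a biological coefficient of variation of 28.0%. Contrasts were tested with the quasi-likelihood F-test, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Fitted fold changes carry a prior count of 0.125. Levels are TMM-scaled counts per 1000000 gene counts (CPM), as mean ± SD of the 2 libraries. Where a group had no counts for a gene, the fold is a lower bound against 3 counts over the group, which is 0.113 CPM in MEF and 0.0667 to 0.0780 CPM in the other groups. These floors cover counting error only. The p-values measure the spread between these samples, and the labels do not say whether replicates were separate cultures or animals.

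The contrasts were iPSC against MEF, each day 3 population against MEF, and the 2 populations of each day against each other. Day 6 was set against day 3 for the Ineff and for the Eff populations. The last were iPSC against d6_Eff and the difference between the Eff against Ineff contrasts of day 6 and day 3. The following 28 gene lists, the tests and the rule for named genes were fixed before the data were examined: sorting markers, reprogramming factors, fibroblast matrix and surface, mesenchymal transcription factors, epithelial, pluripotency, primed epiblast and early lineage, germline, DNA replication and G1/S, mitosis and G2/M, p53 targets and cell cycle inhibitors, interferon response, inflammation and secreted factors, TGF-beta and YAP targets, Myc targets and ribosome biogenesis, glycolysis, oxidative phosphorylation, DNA methylation enzymes, Polycomb and histone modifiers, imprinted genes, immediate early and dissociation stress, hypoxia and glucose stress, and markers of leukocytes, endothelium, skeletal muscle, smooth muscle, neural and glial cells, and epidermal keratinocytes. Lists were tested with camera at a preset correlation of 0.01, which compares a list with all other genes, adjusted over all 252 tests of a list in a comparison. An estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction, were run beside it. Of the 252 tests, 126 were called by camera, 41 of these also with the estimated correlation, and fry called 154.

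For iPSC against MEF and for the comparisons between the 2 populations of 1 day, the 8 called genes with the largest positive and the 8 with the largest negative log2 fold change were named, and for other comparisons 4 and 4. A gene was eligible when every library of the higher group held at least 5 CPM and lay above every library of the lower group. In the difference between days, the highest group mean had to reach 5 CPM. Predicted genes, pseudogenes, ribosomal protein genes and small RNAs were excluded. From each list, up to 3 called members per direction with the smallest adjusted p were named, as were the sorting markers, the reprogramming factors and members that went against their list. The text prints a part of these genes.

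Genes called between iPSC and MEF with at least a 4-fold change formed an iPSC-high and a MEF-high set, which were followed through the sorted groups on log2 CPM with a prior count of 2. Genes outside the MEF-to-iPSC range were those called in the same direction against both MEF and iPSC with at least a 2-fold change.

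Alternatives were RLE size factors, no filter, DESeq2 1.42.0, only the groups compared, the replicate number as a block, no genes with overlapping annotation, other fold minimums and prior counts, and leaving out each library in turn, in which case the lone library of its group is assumed to vary like the others. Leaving out MEF replicate 2 and d6_Eff replicate 2 together, and the share of reads outside genes as a covariate, were added after seeing the data. The fit was tested on simulated data built from these counts, with 50 changed genes per fold. Each gene was given the same dispersion in all groups, so the wider spread of the MEF pair was not simulated. The SD of log2 ratios between replicates was 0.871 in MEF and 0.221 to 0.325 in the other groups. The rates that follow therefore hold for equal spread only. At 4-fold, 92%, 92% and 86% of the changed genes were recovered in the day 3, day 6 and iPSC against MEF contrasts, and at 2-fold 18%, 14% and 18%, with 2, 7 and 11 false calls. Figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Other data on these cells were not used here.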

Results

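Gene expression was measured by poly-A RNA-seq in 12 libraries of mouse cells, with 2 replicates in each of 6 groups. The groups were mouse embryonic fibroblasts (MEF), the starting cells, induced pluripotent stem cells (iPSC), the end point, and 4 populations sorted from reprogramming cultures. All sorted cells carried SSEA1, a surface carbohydrate of pluripotent cells. On day 3, d3_Ineff cells lacked CD73 and carried Sca1, and d3_Eff cells carried CD73 and lacked Sca1. On day 6, d6_Ineff cells lacked EpCAM and carried Sca1, and d6_Eff cells carried EpCAM and lacked Sca1. CD73 is an ectonucleotidase encoded by Nt5e (ENSMUSG00000032420), Sca1 a membrane-anchored surface protein encoded by Ly6a (ENSMUSG00000075602), and EpCAM an epithelial adhesion molecule encoded by Epcam (ENSMUSG00000045394). MEF grew in MEF medium, iPSC in ES medium, and the reprogramming cultures in ES medium with dox and AA, so medium differed with the group.

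Reads assigned to genes numbered 20978376 and 9284060 in MEF replicates 1 and 2, 22476813 and 22506808 in d3_Ineff, and 22527160 and 19801224 in d3_Eff. The totals were 16081124 and 22763548 in d6_Ineff, 20730460 and 16255091 in d6_Eff, and 22577091 and 14911103 in iPSC. Reads outside genes made up 47.2% of the uniquely placed reads in MEF replicate 2 and 24.1% in d6_Eff replicate 2, against 5.10% to 11.7% in the other 10 libraries. Lars2, a mitochondrial leucyl-tRNA synthetase, took 5.25% of the gene counts of MEF replicate 2, 1.34% of d6_Eff replicate 2 and at most 0.421% elsewhere. Across genes, the replicate correlation (Pearson r of log2 CPM) was 0.948 in MEF and 0.987 to 0.992 in the other 5 groups. Over genes with a mean log2 CPM above 2 in the pair, r was 0.877 in MEF and 0.980 to 0.990 in the others.

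The comparison of iPSC with MEF set the start and the end of the course side by side. Utf1, a chromatin-associated factor of pluripotent cells, had 554 ± 18.3 CPM (SD, n = 2) in iPSC and no counts in MEF, at least 4903-fold higher (adjusted p = 1.06e-07). L1td1, an RNA-binding protein of pluripotent cells, rose from 0.261 ± 0.223 to 428 ± 8.65 CPM (log2 fold change 11.06 ± 0.37, SE, adjusted p = 1.55e-08). Fibroblast genes went the other way. Vim, the intermediate filament protein of mesenchymal cells, fell from 6577 ± 362 to 106 ± 2.44 CPM (adjusted p = 5.90e-08), and the hyaluronan receptor gene Cd44 from 365 ± 12.5 to 0.605 ± 0.482 CPM (adjusted p = 3.87e-08).

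Of 16240 genes tested between iPSC and MEF, 4221 were higher and 4336 lower in iPSC (adjusted p under 0.05). The largest rises were in Utf1, the testis RNA-binding protein gene Rbmxl2 (at least 1993-fold), the stem cell factor receptor gene Kit (at least 1176-fold), the nuclear receptor gene Nr0b1 (at least 1168.0-fold), the adaptor gene Grb7 (at least 893-fold), Dppa4 (at least 883-fold), Tdgf1 and the transcription factor gene Olig1 (at least 796-fold). Tdgf1, a coreceptor of Nodal, had 1184 ± 8.79 CPM in iPSC and 2 counts in MEF. The largest falls were in the chemokine gene Cxcl5 (at least 3241.0-fold), the Wnt agonist gene Rspo2 (at least 2083-fold), the leukocyte adhesion gene Vcam1 (at least 1701-fold), the guidance gene Sema3a (at least 1518.0-fold), Masp1, Fibin, Adam12 and Fam20a (at least 1046-fold each).

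Among the fixed lists, 43 of 46 pluripotency genes rose from MEF to iPSC and 3 were not called (44 rose adjusted over the list alone; camera adjusted p = 9.69e-56). All 40 fibroblast matrix and surface genes fell (40 over the list alone; adjusted p = 8.47e-32, and adjusted p = 0.0881 with an estimated correlation). Among 41 mesenchymal transcription factors, 36 fell and none rose by edgeR, with 1 up and 38 down adjusted over the list alone (adjusted p = 4.31e-15, and 0.0630 as adjusted p with an estimated correlation). Epithelial genes rose in 33 of 40 cases and fell in 2 (33 and 3 over the list alone; adjusted p = 5.69e-22). Epcam rose from 0.284 ± 0.401 to 369.5 ± 30.6 CPM (log2 fold change 9.84 ± 0.44, adjusted p = 4.44e-08), while the simple keratin genes Krt7 and Krt19 fell. DNA replication genes rose in 29 of 30 cases and fell in 1 (29 and 1 over the list alone; adjusted p = 4.82e-15), with Mcm5, a subunit of the replicative helicase, at 81.4 ± 5.98 and 585 ± 7.95 CPM. Mitosis genes rose in 28 of 30 (28 over the list alone; adjusted p = 1.55e-10), and Polycomb and histone modifiers in 24 of 34 with 2 lower (24 and 2; adjusted p = 5.95e-07, and adjusted p = 0.0722 with an estimated correlation). Of 31 Myc target and ribosome biogenesis genes, 28 rose and 3 were not called (31 rose over the list alone; adjusted p = 2.39e-07, and adjusted p = 0.0815 with an estimated correlation).

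Germline genes rose in 22 of 27 cases (24 over the list alone; adjusted p = 6.29e-07, and adjusted p = 0.0610 with an estimated correlation). Ddx4, a germ cell RNA helicase, was at 0.713 ± 0.571 CPM in MEF and 34.2 ± 0.589 in iPSC. DNA methylation enzymes rose in 11 of 19 and fell in 4 (11 and 4 over the list alone; adjusted p = 0.00143, and adjusted p = 0.331 with an estimated correlation). Tet1, a methylcytosine dioxygenase, rose from 3.29 ± 0.310 to 342 ± 14.4 CPM (adjusted p = 1.92e-08). All 12 smooth muscle genes fell (12 over the list alone; adjusted p = 1.36e-09), as did 22 of 24 TGF-beta and YAP targets with 2 higher (22 and 2; adjusted p = 2.46e-20, and adjusted p = 0.0707 with an estimated correlation). Skil, a Smad corepressor gene, was 1 of the 2 that rose (log2 fold change 0.95 ± 0.17, adjusted p = 5.68e-04). Inflammation and secreted factors fell in 24 of 33 and rose in 1 (25 and 1 over the list alone; adjusted p = 1.55e-10, and adjusted p = 0.111 with an estimated correlation). Among 27 p53 targets and cell cycle inhibitors, 14 fell and 4 rose (14 and 5 over the list alone; adjusted p = 0.00113). Glycolysis genes rose in 12 of 19 with 1 lower (12 and 1; adjusted p = 0.00387, and adjusted p = 0.0754 with an estimated correlation).

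Of 18 primed epiblast and early lineage genes, 9 rose and 2 fell (9 and 2 over the list alone; adjusted p = 0.0192, and adjusted p = 0.106 with an estimated correlation). This call was lost without MEF replicate 2 (adjusted p = 0.0511) or iPSC replicate 2 (adjusted p = 0.0520). Imprinted genes fell in 12 of 24 and rose in 5 (13 and 5; adjusted p = 0.0459, and adjusted p = 0.289 with an estimated correlation), a call lost in each of the 12 refits without 1 library (adjusted p = 0.0510 to 0.0895). Of the 4 reprogramming factors, 3 rose and Myc fell (3 and 1; adjusted p = 0.00616, and adjusted p = 0.249 with an estimated correlation). That call was lost without MEF replicate 1 (adjusted p = 0.147) or 2 (0.188), d6_Eff replicate 1 (0.0617) or iPSC replicate 2 (0.0520). Camera did not call the interferon response (3 up, 12 down of 33), oxidative phosphorylation (9 up of 33), immediate early (4 up, 7 down of 22), hypoxia and glucose stress (6 up, 7 down of 18), leukocyte (3 up, 3 down of 10), endothelial (6 up, 3 down of 13), skeletal muscle (2 up, 2 down of 10), neural (8 up, 3 down of 18) or keratinocyte list (2 up, 3 down of 10). Adjusted over the list alone, these counts were 3 and 12, 8 and 0, 4 and 7, 6 and 7, 3 and 4, 6 and 4, 2 and 2, 9 and 3, and 2 and 1. Without MEF replicate 2, the library with 47.2% of reads outside genes, the oxidative phosphorylation list was called higher in iPSC (adjusted p = 9.56e-06) and the immediate early list was called as well (adjusted p = 0.0486). The neural list was called in 6 of the 12 refits without 1 library (adjusted p = 0.0315 to 0.0494). The count of changed genes stayed within 1.5 times of the reported one without each library.

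**Figure D1:**
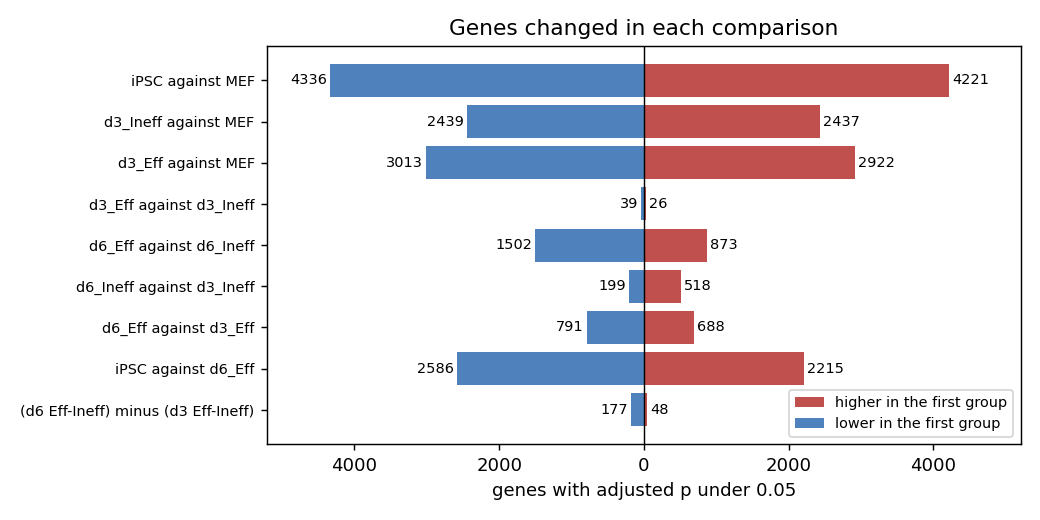
Bars give the number of genes called higher (to the right) and lower (to the left) in each of 9 comparisons. Calls are by edgeR at an adjusted p under 0.05, out of 16240 genes tested. The d3_Eff against d3_Ineff comparison had 26 higher and 39 lower genes, and d6_Eff against d6_Ineff 873 and 1502.

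Each day 3 population was compared with MEF to describe the first days of reprogramming. Both had the transcripts of the reprogramming factors, of which Sox2 was at 3.47 ± 1.15 CPM in MEF, 148 ± 63.4 in d3_Ineff and 236 ± 7.66 in d3_Eff (adjusted p = 1.34e-06 and 5.40e-07 against MEF). The files do not separate introduced from native copies of these genes. Proliferation genes rose in both, and Rrm1, the large subunit of ribonucleotide reductase, went from 183 ± 6.41 CPM to 947 ± 18.8 in d3_Ineff and 971 ± 79.9 in d3_Eff. Matrix genes fell in both, and Sparc, a matrix glycoprotein gene, was at 5774 ± 1227 CPM in MEF and 569.5 ± 106 in d3_Eff (log2 fold change -3.34 ± 0.24, adjusted p = 2.38e-06). Ly6a was higher in d3_Ineff than in MEF (754 ± 162 against 149 ± 52.5 CPM, adjusted p = 2.24e-04), and Nt5e was lower (3.33 ± 1.12 against 29.8 ± 4.89 CPM, adjusted p = 6.34e-05). The d3_Ineff cells were sorted for Sca1 and against CD73, so both differences can follow from the gate.

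In d3_Ineff, 2437 genes were higher and 2439 lower than in MEF, and in d3_Eff 2922 were higher and 3013 lower. Pcsk1n, an inhibitor of a prohormone convertase, and the adhesion gene Ceacam1 were among the 4 largest rises in both, with no counts in MEF and at least 314-fold and 271-fold higher levels in d3_Ineff and 635-fold and 471.5-fold in d3_Eff. Others were Tmprss5 and Cacna2d2 in d3_Ineff, and Dmrtc2 (at least 599.9-fold) and the hormone gene Trh in d3_Eff. Ndufa4l2, a mitochondrial protein gene induced by hypoxia, was at 57.0 ± 8.08 CPM in MEF and had no counts in either day 3 group, at least 854-fold and 803.5-fold lower in d3_Ineff and d3_Eff. Tenomodulin (Tnmd), Plac8 and Fabp4 in d3_Ineff, and Edil3 (at least 1573-fold), Mogat2 and the interleukin receptor gene Il1rl1 in d3_Eff were the other largest falls.

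Fibroblast matrix and surface genes fell in 36 of 40 cases in each day 3 group (36 and 38 over the list alone in d3_Ineff and d3_Eff; adjusted p = 9.82e-18 and 3.93e-19). With an estimated correlation these calls were lost (adjusted p = 0.159 and 0.150). Mesenchymal transcription factors fell in 22 and 27 of 41 and rose in 6 and 5 (24 and 29 down, 6 and 5 up over the list alone; adjusted p = 2.22e-04 and 5.92e-05, and adjusted p = 0.286 and 0.249 with an estimated correlation). Id1 and Id2, inhibitors of helix-loop-helix factors and targets of BMP signalling, were among the members that rose, with Id1 at 20.9 ± 0.576 CPM in MEF, 335 ± 2.39 in d3_Ineff and 279.5 in d3_Eff. DNA replication genes rose in 27 and 28 of 30 (27 and 28 over the list alone; adjusted p = 1.02e-15 and 2.88e-17), and mitosis genes in 26 and 27 of 30 (27 and 28; adjusted p = 7.94e-13 and 6.94e-14). Epithelial genes rose in 19 and 20 of 40 and fell in 2 and 3 (21 and 20 up, 3 and 3 down over the list alone; adjusted p = 9.43e-06 and 1.93e-05). Cdh1, the gene of E-cadherin, had 1 count in MEF and 18.3 ± 0.280 CPM in d3_Ineff and 17.4 ± 4.16 in d3_Eff. Pluripotency genes rose in 22 and 23 of 46 and fell in 2 and 4 (22 and 25 up, 2 and 4 down over the list alone; adjusted p = 9.60e-06 and 1.59e-06; adjusted p = 0.0485 and 0.0569 with an estimated correlation). L1td1 reached 512 ± 23.9 and 539 ± 57.2 CPM, while Klf2, a factor of the naive state, fell from 45.3 ± 3.84 to 3.14 ± 0.422 and 3.71 ± 0.409 CPM.

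TGF-beta and YAP targets fell in 17 and 18 of 24 (17 and 20 over the list alone, with 1 higher in d3_Ineff; adjusted p = 2.10e-07 and 2.42e-10, and adjusted p = 0.249 and 0.175 with an estimated correlation). Glycolysis genes fell in 12 and 11 of 19 and rose in 2 and 2 (13 and 11 down, 2 and 2 up over the list alone; adjusted p = 5.90e-05 and 6.48e-04). The lactate exporter gene Slc16a3 fell from 331 ± 60.02 to 0.910 ± 0.135 CPM in d3_Ineff and 0.368 ± 0.214 in d3_Eff, while the glucose transporter gene Slc2a3 rose from 20.2 ± 2.95 to 118 ± 9.05 and 123 ± 27.4 CPM. Hypoxia and glucose stress genes fell in 12 and 13 of 18 and rose in 2 and 2, with the same counts over the list alone (adjusted p = 5.62e-07 and 3.48e-06). Bnip3, a hypoxia-induced mitophagy gene, was at 292 ± 70.5 CPM in MEF, 19.8 ± 3.06 in d3_Ineff and 13.8 ± 0.999 in d3_Eff. Camera also called 6 lists in both day 3 groups, given here as d3_Ineff and d3_Eff, with the estimated-correlation value last. They were higher for reprogramming factors (4 and 4 of 4 rose; adjusted p = 6.65e-05 and 6.72e-05; 0.140 and 0.130). Myc targets (23 and 27 of 31; adjusted p = 1.03e-08 and 4.36e-10; 0.0648 and 0.0546) were higher as well. So were Polycomb and histone modifiers (21 and 22 of 34; adjusted p = 1.22e-07 and 1.38e-08; 0.0598 and 0.0485). Lists were lower for inflammation and secreted factors (13 and 19 of 33 fell, 3 and 3 rose; adjusted p = 1.37e-04 and 2.00e-06; 0.293 and 0.203) and the interferon response (11 and 16 of 33 fell, 3 and 3 rose; adjusted p = 0.00993 and 0.00111; 0.307 and 0.207). Smooth muscle genes were lower too (10 and 9 of 12 fell, 1 and 0 rose; adjusted p = 1.22e-04 and 2.63e-06; 0.0785 and 0.0546). Over the list alone, these 6 lists had 4 and 4, 28 and 30, and 21 and 22 genes up, and then 15 and 21, 11 and 18, and 10 and 11 down. The interferon call in d3_Ineff was lost without MEF replicate 1 (adjusted p = 0.0815). In d3_Ineff alone, p53 targets and cell cycle inhibitors were called higher (10 of 27 rose and 2 fell, 11 and 2 over the list alone; adjusted p = 0.0420, and adjusted p = 0.129 with an estimated correlation), a call lost without d3_Ineff replicate 2 (adjusted p = 0.0657). In d3_Eff alone, the immediate early list was lower (8 of 22 fell and 3 rose, the same over the list alone; adjusted p = 0.0333, and adjusted p = 0.5835 with an estimated correlation), a call lost without MEF replicate 1 (adjusted p = 0.2345). Sorting markers were called higher in d3_Eff (2 of 5 rose and 1 fell, the same over the list alone; adjusted p = 0.0439, and adjusted p = 0.307 with an estimated correlation), a call lost in 5 of the 12 refits. The list of sorting markers holds the genes of the gates, so its call can follow from the sort. Of the imprinted genes the list test called neither direction. H19, a growth-associated non-coding RNA, rose from 1383 ± 441 to 14228 ± 1408 and 18006 ± 3155 CPM. Laptm5, a lysosomal protein gene counted here among leukocyte markers, rose from 0.695 ± 0.399 to 336 ± 39.1 and 260 ± 0.484 CPM, while 2 and 4 of the 10 leukocyte markers fell, Lyz2 in both groups. Without d3_Ineff replicate 1 or 2 the count against MEF dropped from 4876 to 2946 and 3005. Without MEF replicate 2 the oxidative phosphorylation list was called higher in d3_Ineff (adjusted p = 4.05e-07) and in d3_Eff (adjusted p = 5.83e-07).

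On day 3, d3_Eff was compared with d3_Ineff, the 2 gates of the same day. The sorted surface proteins were followed by their transcripts, with Nt5e at 37.2 ± 6.10 CPM in d3_Eff and 3.33 ± 1.12 in d3_Ineff (log2 fold change 3.48 ± 0.36, adjusted p = 0.00282). Ly6a was at 82.1 ± 2.79 and 754 ± 162 CPM (log2 fold change -3.20 ± 0.32, adjusted p = 0.00282). Trh, the gene of thyrotropin-releasing hormone, was higher in d3_Eff (395 ± 39.8 against 71.4 ± 4.91 CPM, log2 fold change 2.47 ± 0.18, adjusted p = 5.55e-04). Nr0b1, a nuclear receptor gene of naive pluripotent cells, was higher as well (22.1 ± 2.20 against 2.78 ± 0.162 CPM, log2 fold change 2.99 ± 0.22, adjusted p = 5.61e-04). None of the 4 reprogramming factor transcripts was called by edgeR, and 1 was higher at an unadjusted p under 0.05. Camera called the list higher in d3_Eff (adjusted p = 0.0237, and adjusted p = 0.407 with an estimated correlation). That call was lost without d3_Eff replicate 1 (adjusted p = 0.119) or d3_Ineff replicate 2 (adjusted p = 0.437). The levels were 80.1 ± 4.20 and 53.2 ± 26.7 CPM for Pou5f1 in d3_Eff and d3_Ineff, 236 ± 7.66 and 148 ± 63.4 for Sox2, 243 ± 29.0 and 165 ± 60.5 for Klf4, and 280.0 ± 32.7 and 256 ± 33.9 for Myc.

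In all, 26 genes were higher and 39 lower in d3_Eff, and 1317 had an unadjusted p under 0.05. Besides those above, the largest rises were in Nptx1, Sox21, Trim9, Myb and Tbx21, of which the last 3 encode a ubiquitin ligase and a pair of blood cell transcription factors. The largest falls besides Ly6a were in Adamts5, an aggrecanase (67.3 ± 1.79 to 14.7 ± 2.00 CPM), the cell cycle inhibitor genes Cdkn1c (143 ± 6.36 to 34.9 ± 6.17 CPM) and Cdkn2b (53.4 ± 3.88 to 14.4 ± 1.94 CPM), Igfbp6, Cited2, Igfbp7 and the water channel gene Aqp1. Of 46 pluripotency genes, 3 rose (8 over the list alone; adjusted p = 9.60e-06): Nr0b1, the nuclear receptor gene Nr5a2 (0.424 ± 0.105 to 5.31 ± 0.948 CPM) and the signalling ligand gene Nodal. None of the 30 DNA replication genes was called by edgeR over all genes or over the list alone, and 11 were higher at an unadjusted p under 0.05. The list as a whole was higher by camera (adjusted p = 1.98e-09). For 30 mitosis genes none was called and 5 were higher at an unadjusted p under 0.05 (adjusted p = 2.17e-05 for the list, and adjusted p = 0.0968 with an estimated correlation). Among the lists lower in d3_Eff were fibroblast matrix and surface (1 of 40 fell, Sparc, and 12 over the list alone; adjusted p = 1.15e-12), TGF-beta and YAP targets (1 of 24, and 11; adjusted p = 4.20e-13) and inflammation and secreted factors (3 of 33, and 8; adjusted p = 8.88e-10). With an estimated correlation their adjusted p was 0.207, 0.123 and 0.123. No smooth muscle gene of 12 was called over all genes by edgeR, 5 were lower at an unadjusted p under 0.05 and 5 fell adjusted over the list alone (adjusted p = 3.37e-06 for the list). Foxd1, a mesenchymal transcription factor gene, rose (39.8 ± 5.54 to 114 ± 17.6 CPM, adjusted p = 0.0480), against the direction of its list (1 up and 3 down over the list alone; adjusted p = 0.00449, and adjusted p = 0.371 with an estimated correlation).

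Camera also called 7 more lists on day 3, each lost with an estimated correlation. Higher in d3_Eff was the list of 5 sorting markers (1 rose and 1 fell, 3 and 1 over the list alone; adjusted p = 0.00107, then 0.120). That list holds the genes of the gates, so its call can follow from the sort. Also higher were Polycomb and histone modifiers (adjusted p = 1.22e-04, then 0.156), Myc targets (adjusted p = 3.63e-04, then 0.202) and epithelial genes (adjusted p = 0.0240, then 0.193). None of the genes of these last 3 lists was called by edgeR over all genes, and 8, 2 and 9 were higher and 0, 0 and 6 lower at an unadjusted p under 0.05. Lower were the interferon response (0 of 33 by edgeR, 1 higher and 2 lower at an unadjusted p under 0.05; adjusted p = 0.0135, then 0.293), p53 targets and cell cycle inhibitors (2 of 27 fell; adjusted p = 0.0185, then 0.0968) and imprinted genes (2 of 24 fell; adjusted p = 0.0304, then 0.300). The epithelial, interferon and imprinted calls were also lost in 4, 3 and 3 of the refits without 1 library.

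The number of day 3 calls changed with the library left out, also for libraries outside the contrast. A refit without 1 day 3 library leaves 1 in its group, so it cannot tell dependence on that library from lost replication. A fit of only the 2 day 3 groups called 700 genes, with all 65 of the main fit among them. The count of 65 became 6 and 4 without d3_Eff replicates 1 and 2, 5 and 5 without d3_Ineff, 10 and 10 without d6_Ineff, 39 and 36 without d6_Eff, and 624 and 644 without MEF replicates 1 and 2. Of 24 named and called genes, only Nr0b1 and Trh were called in each of the 12 refits without 1 library (highest adjusted p = 0.0273 for each). The Nt5e call was lost without d3_Ineff replicate 1 (adjusted p = 0.0666), the Cdkn1c call without d3_Eff replicate 1 (adjusted p = 0.0581), and the Ly6a call without either d3_Eff library (highest adjusted p = 0.1405).

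**Figure D2:**
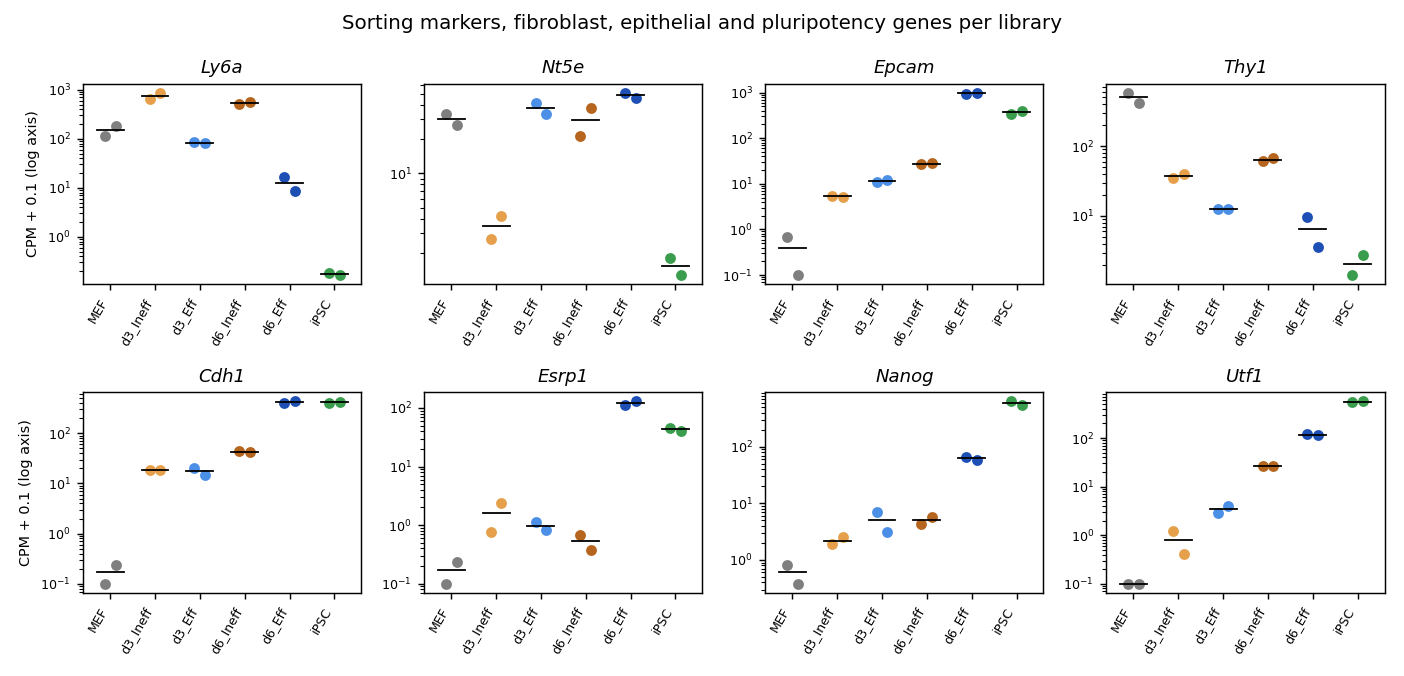
Points show TMM-scaled CPM (log axis, 0.1 added) of 8 genes in each of the 12 libraries, and bars mark the mean of the 2 libraries of a group. Ly6a fell to 12.3 CPM in d6_Eff and Epcam reached 971 CPM there, while Nanog and Utf1 were at 63.0 and 118 CPM in d6_Eff and at 596 and 554 CPM in iPSC.

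On day 6 the sorted populations were compared in the same way. Cells of d6_Eff had an epithelial profile. Epcam was at 971 ± 33.1 CPM in d6_Eff and 27.8 ± 0.102 in d6_Ineff (log2 fold change 5.13 ± 0.32, adjusted p = 1.90e-05). EpCAM was part of the gate, so this difference can follow from the sort. The tight junction gene Cldn7 was at 171 ± 5.39 against 0.732 ± 0.358 CPM (log2 fold change 7.91 ± 0.48, adjusted p = 1.90e-05), and Esrp1, an epithelial splicing regulator, at 121 ± 10.4 against 0.429 ± 0.212 CPM (adjusted p = 3.57e-05). In d6_Ineff Vim was at 4101 ± 171 CPM, against 458 ± 116 in d6_Eff (log2 fold change -3.16 ± 0.24, adjusted p = 3.89e-05) and Acta2, the smooth muscle actin gene, at 796 ± 23.9 against 49.0 ± 27.2 CPM (adjusted p = 2.62e-04). Nanog, a core pluripotency factor, was at 63.0 ± 6.43 CPM in d6_Eff and 4.97 ± 1.04 in d6_Ineff (log2 fold change 3.66 ± 0.37, adjusted p = 1.64e-04).

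Between the day 6 populations, 873 genes were higher and 1502 lower in d6_Eff. Among the largest rises, Bnipl (at least 125-fold), Tmem54 (at least 123-fold), the membrane protrusion gene Prom2 (at least 114-fold) and Ceacam19 (at least 90.6-fold) had no counts in d6_Ineff. B4galnt3, a glycosyltransferase gene, had 1 count there and 9.08 ± 0.708 CPM in d6_Eff. The others were Esrp1, Cldn7 and the phospholipase gene Plch2. Of 87 named and called genes, 29 lost their call in some refit without 1 library, and the Ceacam19 call was lost in 4. The largest falls were in Rgs7bp, the smooth muscle gene Lmod1 (7.35 ± 0.888 to 0.134 CPM), Ly6a (535 ± 22.0 to 12.3 ± 5.41 CPM, log2 fold change -5.43 ± 0.36, adjusted p = 2.59e-05), the sarcoglycan gene Sgcd, Masp1, Atoh8 (24.1 ± 1.30 to 0.658 ± 0.266 CPM), Rin3 and the laminin gene Lama3. Nt5e, the gate of day 3, was not called (48.4 ± 3.31 and 29.0 ± 11.2 CPM in d6_Eff and d6_Ineff, adjusted p = 0.151). None of the 4 reprogramming factors was called by edgeR or had an unadjusted p under 0.05, with Pou5f1 at 88.3 ± 22.6 and 70.2 ± 0.246 CPM and Sox2 at 231 ± 18.1 and 177 ± 9.76 CPM.

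Of 40 epithelial genes, 28 rose and 12 were not called (29 up and 1 down over the list alone, adjusted p = 9.24e-27). Epcam, a gene of the gate, is among these 40. Fibroblast matrix and surface genes fell in 31 of 40 (34 over the list alone; adjusted p = 2.31e-19, and adjusted p = 0.124 with an estimated correlation), and mesenchymal transcription factors in 17 of 41 (20 down and 1 up over the list alone; adjusted p = 1.58e-09, and adjusted p = 0.0801 with an estimated correlation). Prrx1, a homeobox factor of limb and stromal mesenchyme, was at 14.2 ± 3.80 CPM in d6_Eff and 125 ± 18.9 in d6_Ineff. Pluripotency genes rose in 18 of 46 and fell in 4 (21 and 4 over the list alone; adjusted p = 1.55e-07). Nr5a2 and Nr0b1 were at 54.3 ± 1.17 and 46.6 ± 1.35 CPM in d6_Eff, against 2.47 ± 1.35 and 2.09 ± 0.0890. Of those lower in d6_Eff, the uridine phosphorylase gene Upp1 went from 22.6 ± 3.65 to 1.69 ± 0.567 CPM (adjusted p = 1.49e-04) and Esrrb, an orphan nuclear receptor of naive cells, from 13.5 ± 0.0277 to 3.07 ± 0.811 CPM (adjusted p = 0.00166).

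DNA replication genes rose in 20 of 30 in d6_Eff (25 up and 1 down over the list alone; adjusted p = 1.08e-14), among them Mcm5 (145 ± 1.83 to 366 ± 28.3 CPM, adjusted p = 4.07e-04). Mitosis genes rose in 13 of 30 (23 over the list alone; adjusted p = 1.66e-10) and Myc target and ribosome biogenesis genes in 15 of 31 (24; adjusted p = 2.39e-11). Among 27 p53 targets and cell cycle inhibitors, 7 fell and 1 rose (7 and 2 over the list alone; adjusted p = 0.00770, and adjusted p = 0.0722 with an estimated correlation), with Cdkn1c, an imprinted cell cycle inhibitor, at 20.8 ± 3.31 against 269 ± 2.79 CPM (log2 fold change -3.70 ± 0.22, adjusted p = 1.90e-05). Imprinted genes fell in 12 of 24 (13 over the list alone; adjusted p = 1.54e-07), with Ndn at 8.17 ± 1.41 and 38.7 ± 2.11 CPM in d6_Eff and d6_Ineff. TGF-beta and YAP targets fell in 18 of 24 (23; adjusted p = 1.11e-15), inflammation and secreted factors in 13 of 33 (15; adjusted p = 1.78e-06) and interferon response genes in 6 of 33 (9; adjusted p = 4.13e-04). With an estimated correlation the adjusted p of these 3 lists was 0.0968, 0.192 and 0.156. The receptor tyrosine kinase gene Axl went from 183 ± 10.6 to 38.3 ± 1.72 CPM and the chemokine gene Ccl2 from 15.8 to 1.67 CPM in d6_Eff. Polycomb and histone modifiers rose in 7 of 34 (7; adjusted p = 3.33e-04, and adjusted p = 0.175 with an estimated correlation). Smooth muscle genes fell in 7 of 12 and rose in 1 (9 and 1 over the list alone; adjusted p = 4.72e-07), and Actg2, an enteric smooth muscle actin gene, was at 61.4 ± 5.20 CPM in d6_Eff and 360.5 ± 29.8 in d6_Ineff. None of the 19 glycolysis genes was called by edgeR, 2 were higher and 4 lower at an unadjusted p under 0.05, and camera did not call the list (adjusted p = 0.439). Oxidative phosphorylation was called higher (1 of 33 rose; adjusted p = 0.0169, and adjusted p = 0.7295 with an estimated correlation). It was not called without d6_Ineff replicate 2 (adjusted p = 0.165) or d6_Eff replicate 2 (adjusted p = 0.0643).

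The count of 2375 changed genes on day 6 became 1352 and 930 without d6_Eff replicates 1 and 2, 1177 and 1102 without d6_Ineff, and 4715 and 4644 without MEF replicates 1 and 2. In d6_Eff replicate 2, 24.1% of reads lay outside genes.

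Day 6 was compared with day 3 for the Ineff and for the Eff populations. The gates differed (CD73 on day 3, EpCAM on day 6), so both comparisons hold a change of gate besides a change of time. This holds for Nt5e, Epcam and genes that go with them. In d6_Ineff, part of the epithelial and pluripotency genes was higher than in d3_Ineff. Spint1, a membrane protease inhibitor of epithelia, rose from 8.52 ± 0.0496 to 99.3 ± 5.71 CPM (log2 fold change 3.54 ± 0.29, adjusted p = 1.50e-04), and Epcam from 5.20 ± 0.188 to 27.8 ± 0.102 CPM (adjusted p = 0.00132). Tet1 rose from 2.58 ± 0.252 to 24.9 ± 0.246 CPM (log2 fold change 3.27 ± 0.22, adjusted p = 4.20e-05) and Utf1 from 0.705 ± 0.549 to 26.2 ± 0.150 CPM (adjusted p = 1.91e-04). Nt5e rose from 3.33 ± 1.12 to 29.0 ± 11.2 CPM (adjusted p = 8.58e-04), while Ly6a was not called (log2 fold change -0.49, adjusted p = 0.424).

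In d6_Ineff, 518 genes were higher and 199 lower than in d3_Ineff. The largest rises were in Wdr86 (at least 116-fold), Ly6h, the neuropeptide receptor gene Crhr2 and the enkephalin precursor gene Penk, and the largest falls in the alcohol dehydrogenase gene Adh7 (33.9 ± 1.26 to 1.55 ± 0.965 CPM), the Notch-ligand-like gene Dlk2, Edn1 and Krt19 (161 ± 1.97 to 31.0 ± 12.8 CPM). The Edn1 call was lost in 2 of the refits without 1 library. Epithelial genes rose in 15 of 40 and fell in 1 (19 and 2 over the list alone; adjusted p = 7.83e-12), and pluripotency genes in 10 of 46 (13; adjusted p = 4.96e-06). DNA replication genes fell in 4 of 30 (16; adjusted p = 8.88e-10), mitosis genes in 4 of 30 (11; adjusted p = 6.36e-09) and Myc target and ribosome biogenesis genes in 3 of 31 (15; adjusted p = 1.91e-10, and adjusted p = 0.0546 with an estimated correlation). Endothelial markers rose in 2 of 13 (5; adjusted p = 0.00547, and adjusted p = 0.203 with an estimated correlation). Interferon response genes rose in 3 of 33 (4; adjusted p = 0.0185, and adjusted p = 0.3195 with an estimated correlation), a call lost without d6_Ineff replicate 2 (adjusted p = 0.0691). Sorting markers were called higher (2 of 5 rose, 2 over the list alone; adjusted p = 0.0271, and adjusted p = 0.249 with an estimated correlation), a call lost in 8 of the 12 refits. The list of sorting markers holds the genes of the gates, so its call can follow from the sort. Oxidative phosphorylation was called lower (adjusted p = 0.0135, and adjusted p = 0.7295 with an estimated correlation), with 0 of 33 genes called by edgeR and 3 lower at an unadjusted p under 0.05. That call was lost without d3_Ineff replicate 2 (adjusted p = 0.173) or d6_Ineff replicate 2 (adjusted p = 0.162). The fibroblast matrix and surface list was not called (6 up and 1 down of 40, 8 and 3 over the list alone; adjusted p = 0.0968). It was called when either MEF library was left out. The count of 717 became 138 and 103 without d3_Ineff replicates 1 and 2, 202 and 181 without d6_Ineff, 446 and 439 without iPSC, and 2607 and 2570 without MEF, and 17 of 67 named and called genes were called in every refit.

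In d6_Eff, 688 genes were higher and 791 lower than in d3_Eff. Vim went from 4732 ± 206 to 458 ± 116 CPM (log2 fold change -3.37 ± 0.24, adjusted p = 2.21e-05) and Cdh2, the gene of N-cadherin, from 33.7 ± 12.7 to 0.749 ± 0.893 CPM. Cdh1 rose from 17.4 ± 4.16 to 413 ± 26.1 CPM (log2 fold change 4.57 ± 0.26, adjusted p = 7.85e-06). The largest rises were in Grb7 (at least 632-fold), the glutathione peroxidase gene Gpx2 (at least 516.0-fold), the tight junction gene Cldn6 (2 counts in d3_Eff and 121 ± 2.47 CPM in d6_Eff) and the X-linked homeobox gene Rhox6 (at least 171-fold). The largest falls were in Adh7 (at least 149-fold), Cdh2, Prss12 and Dlk2 (66.3 ± 4.79 to 1.72 ± 0.849 CPM). Epithelial genes rose in 29 of 40 (33 over the list alone; adjusted p = 2.30e-42), and pluripotency genes rose in 23 of 46 and fell in 2 (25 and 3; adjusted p = 3.13e-14), with Utf1 at 3.32 ± 0.826 and 118 ± 4.79 CPM. Mesenchymal transcription factors fell in 13 of 41 (18; adjusted p = 1.86e-08) and TGF-beta and YAP targets in 9 of 24 (17 down and 2 up over the list alone; adjusted p = 1.70e-09). Fibroblast matrix and surface genes fell in 13 of 40 and rose in 1 (16 and 2; adjusted p = 3.45e-06). With an estimated correlation the adjusted p of these 3 lists was 0.0968, 0.182 and 0.420. Imprinted genes fell in 7 of 24 (9; adjusted p = 1.48e-04, and adjusted p = 0.103 with an estimated correlation), and H19 was at 18006 ± 3155 CPM in d3_Eff and 3118 ± 506 in d6_Eff. DNA replication genes were not called as a list (1 of 30 fell, 1 over the list alone; adjusted p = 0.794). Keratinocyte genes rose in 4 of 10 (5; adjusted p = 7.64e-04, and adjusted p = 0.0539 with an estimated correlation). Smooth muscle genes fell in 5 of 12 and rose in 2 (7 and 2; adjusted p = 0.00332, and adjusted p = 0.118 with an estimated correlation). Skeletal muscle genes rose in 2 of 10 (2; adjusted p = 0.0137, and adjusted p = 0.230 with an estimated correlation). Inflammation and secreted factors fell in 7 of 33 and rose in 1 (10 and 1; adjusted p = 0.00405, and adjusted p = 0.423 with an estimated correlation), a call lost without d6_Eff replicate 2 (adjusted p = 0.0742). Among the keratinocyte genes was Col17a1, a hemidesmosomal collagen gene, at 2.302 ± 0.976 and 60.2 ± 18.9 CPM. The count of 1479 became 703 and 751 without d3_Eff replicates 1 and 2, 657 without d6_Eff replicate 2, and 2958 and 2879 without MEF.

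The Eff against Ineff difference of day 6 was then tested against that of day 3, although the gates differed (CD73 on day 3, EpCAM on day 6). Here 48 genes were higher and 177 lower on day 6 than on day 3, with Epcam and Cdh1 among those higher and Ly6a, Vim and Prrx1 among those lower. This count of 225 became 53 and 48 without d3_Eff replicates 1 and 2, 24 and 22 without d3_Ineff, 20 without d6_Eff replicate 2, 52 and 28 without d6_Ineff, and 1349 and 1311 without MEF. Of 39 genes lower in d3_Eff, 38 were also called lower in d6_Eff, and of 26 higher in d3_Eff, 14 were called higher and 4 lower in d6_Eff. Independent lists of these sizes would share 3.61 and 1.40 genes. Both contrasts set cells without Sca1 against cells with Sca1, so the overlap can follow from this shared part of the gates. Across the 16240 genes, which are not independent replicates, log2 fold changes of the day 3 and day 6 contrasts correlated with Pearson r = 0.231 and Spearman rho = 0.359, 1 of 6 such correlations. Over genes at 5 CPM or more r was 0.516.

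The position of the sorted groups between MEF and iPSC was measured on 2060 iPSC-high and 2321 MEF-high genes, sets that were chosen on the MEF and iPSC libraries of this series. For iPSC-high genes, the median share of the log2 distance from MEF to iPSC was 30.6% ± 1.11 (SD, n = 2) in d3_Ineff, 33.5% ± 0.648 in d3_Eff, 41.0% ± 0.515 in d6_Ineff and 59.9% ± 0.554 in d6_Eff. For MEF-high genes it was 37.5% ± 0.0150, 48.4% ± 2.04, 35.0% ± 0.424 and 66.2% ± 2.67 in the same order. Each SD is between the 2 libraries of a sorted group and leaves out the spread of the MEF and iPSC libraries. Shares also moved with prior counts of 0.5 and 5 and without either iPSC library. Between the day 6 populations, 358 iPSC-high genes were higher and 83 lower in d6_Eff (adjusted p = 1.49e-09, and adjusted p = 0.0526 with an estimated correlation), and 845 MEF-high genes were lower and 23 higher (adjusted p = 3.20e-34). From d3_Ineff to d6_Ineff, 177 iPSC-high genes rose and 26 fell (adjusted p = 3.59e-06, and adjusted p = 0.114 with an estimated correlation), while the MEF-high set was not called (97 up, 57 down, adjusted p = 0.679). On day 3 the MEF-high set was lower in d3_Eff (28 down, 5 up, adjusted p = 4.99e-15) and the iPSC-high set higher (13 up, 0 down, adjusted p = 4.22e-05, and adjusted p = 0.139 with an estimated correlation). The order of d3_Ineff and d3_Eff on iPSC-high genes turned with sets from 16-fold changes (12.4% and 9.84%), and without MEF replicate 1 the 4 shares were 53.9%, 59.8%, 60.8% and 77.0%.

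**Figure D3:**
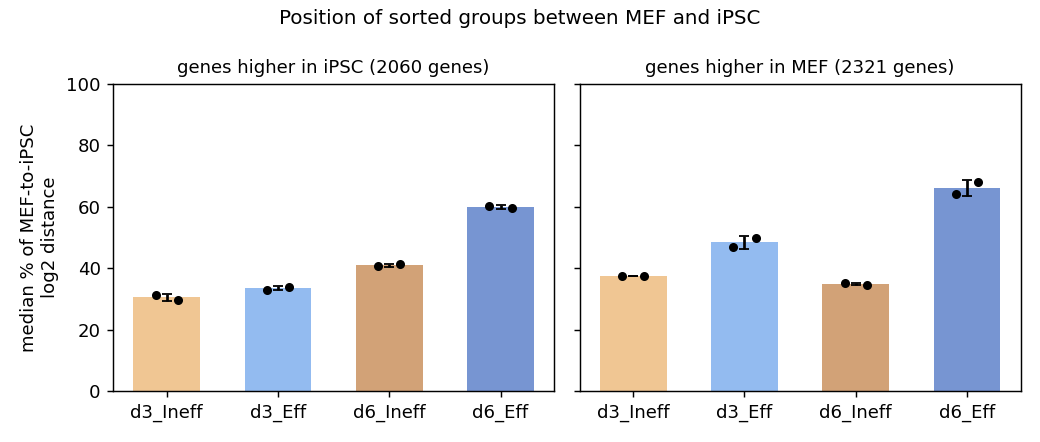
Bars show, for each sorted group, the mean over 2 libraries of the median percentage of the MEF-to-iPSC log2 distance, for 2060 iPSC-high and 2321 MEF-high genes, with the SD as error bars and the libraries as dots. The d6_Eff bars stand at 59.9% and 66.2% and the d6_Ineff bars at 41.0% and 35.0%.

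iPSC were compared with d6_Eff to find what still separated the day 6 cells from the end point. Late pluripotency and germline genes were high in iPSC. Klf2 was at 254 ± 17.7 CPM in iPSC and 2.29 ± 0.838 in d6_Eff (log2 fold change 6.81 ± 0.30, adjusted p = 2.17e-07), and Tdgf1 at 1184 ± 8.79 and 4.82 ± 1.40 CPM (log2 fold change 7.95 ± 0.41, adjusted p = 3.76e-07). Pou5f1 was at 611 ± 48.4 and 88.3 ± 22.6 CPM (adjusted p = 1.08e-04), while Myc fell from 239 ± 1.59 to 11.1 ± 0.0939 CPM (adjusted p = 7.99e-07). The glucose transporter gene Slc2a1 rose from 146 ± 0.767 to 1320 ± 105 CPM (log2 fold change 3.17 ± 0.18, adjusted p = 5.92e-07). Of 5 sorting marker genes, 4 were lower in iPSC (4 over the list alone, adjusted p = 0.00101, and adjusted p = 0.124 with an estimated correlation). Nt5e was at 1.45 ± 0.377 CPM and Epcam at 369.5 ± 30.6 CPM, against 48.4 ± 3.31 and 971 ± 33.1 in d6_Eff. The d6_Eff cells were sorted for EpCAM, so their Epcam level can follow from the gate.

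In iPSC, 2215 genes were higher and 2586 lower than in d6_Eff. Dppa4 (at least 1314-fold), the testis factor gene Dmrt1 (at least 888-fold), A2m (at least 871-fold) and Myo1f (at least 708.0-fold) rose most, and the tachykinin gene Tac2 (at least 1834-fold), the proton pump gene Atp12a (at least 576.5-fold), Stac and Sv2b fell most. Pluripotency genes rose in 39 of 46 (39 over the list alone; adjusted p = 4.86e-32) and germline genes in 17 of 27 (19; adjusted p = 3.96e-11), with the piRNA pathway gene Tdrd12 at 73.8 ± 4.41 and 0.678 ± 0.203 CPM. Glycolysis genes rose in 17 of 19 (17; adjusted p = 4.53e-15), with Slc16a3 at 172 ± 18.3 against 5.44 ± 1.63 CPM and the phosphofructokinase gene Pfkp at 317.5 ± 27.2 against 10.9 ± 0.900 CPM. Hypoxia and glucose stress genes rose in 12 of 18 and fell in 1 (13 and 2; adjusted p = 2.45e-07), with Bnip3 at 279 ± 33.3 against 16.3 ± 1.92 CPM and the fall in Nqo1, a quinone reductase. Among p53 targets and cell cycle inhibitors, 15 of 27 fell (17 down and 1 up over the list alone; adjusted p = 2.10e-07), including Cdkn2a (133 ± 20.6 to 16.9 ± 0.138 CPM), the locus of the p16 and Arf inhibitors. Fibroblast matrix and surface genes fell in 25 of 40 and rose in 3 (26 and 6; adjusted p = 5.64e-08, and adjusted p = 0.367 with an estimated correlation). Primed epiblast and early lineage genes rose in 9 of 18 and fell in 3 (14 and 3; adjusted p = 5.17e-04). TGF-beta and YAP targets fell in 14 of 24 and rose in 3 (adjusted p = 5.25e-04). Mesenchymal transcription factors fell in 14 of 41 and rose in 2 (adjusted p = 0.00324), and inflammation and secreted factors fell in 13 of 33 and rose in 3 (adjusted p = 0.00808). The last 3 lists had the same counts over the list alone. With an estimated correlation these 4 calls were lost (adjusted p = 0.170, 0.427, 0.351 and 0.463), and the inflammation call also without d6_Eff replicate 1 (adjusted p = 0.0617). The keratinocyte list was lower (3 of 10 fell and 2 rose, 4 and 2 over the list alone; adjusted p = 0.0271, and adjusted p = 0.129 with an estimated correlation), a call lost in 11 of the 12 refits without 1 library. Without d6_Eff replicate 2 the count of 4801 became 3149, and without iPSC replicates 1 and 2 it was 2834 and 2858.

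Genes outside the MEF-to-iPSC range, called in the same direction against both with at least a 2-fold change, were counted to find states that belong to neither end. They numbered 1088 in d3_Ineff (645 higher, 443 lower), 1287 in d3_Eff (691 and 596), 1208 in d6_Ineff (844 and 364) and 1160 in d6_Eff (636 and 524). Tac2 had no counts in MEF or iPSC and reached 119 ± 11.1 CPM in d6_Ineff and 143 ± 14.3 in d6_Eff. Pax7, a paired-box factor of muscle and neural crest precursors, was at 59.1 ± 2.20 CPM in d6_Eff and 14.4 ± 2.21 in d6_Ineff, and Ly6d, a surface protein of lymphoid and epithelial progenitors, at 24.2 CPM in d6_Eff. Kpna7, an oocyte importin gene, peaked on day 3 (10.7 ± 0.804 CPM in d3_Eff), and Atp12a was at 20.3 ± 2.97 to 62.1 ± 10.7 CPM in the 4 groups. Cytl1 and the water channel gene Aqp4 were at 14.4 ± 0.325 and 14.4 ± 1.71 CPM in d6_Ineff. On the lower side stood Ndufa4l2 (57.0 ± 8.08 CPM in MEF, 72.5 ± 10.1 in iPSC and at most 1.61 ± 1.46 in a sorted group), Slc16a3 (at most 5.44 ± 1.63) and the mitochondrial gene Mgarp (11.7 ± 3.85 and 28.7 ± 0.657 CPM at the ends and at most 0.549 ± 0.0430 between). Gjb5, a connexin gene, was at 25.8 ± 10.3 and 35.1 ± 0.888 CPM at the ends and had no counts in d6_Eff. No count changed by over 1.5 times without any single library.

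**Figure D4:**
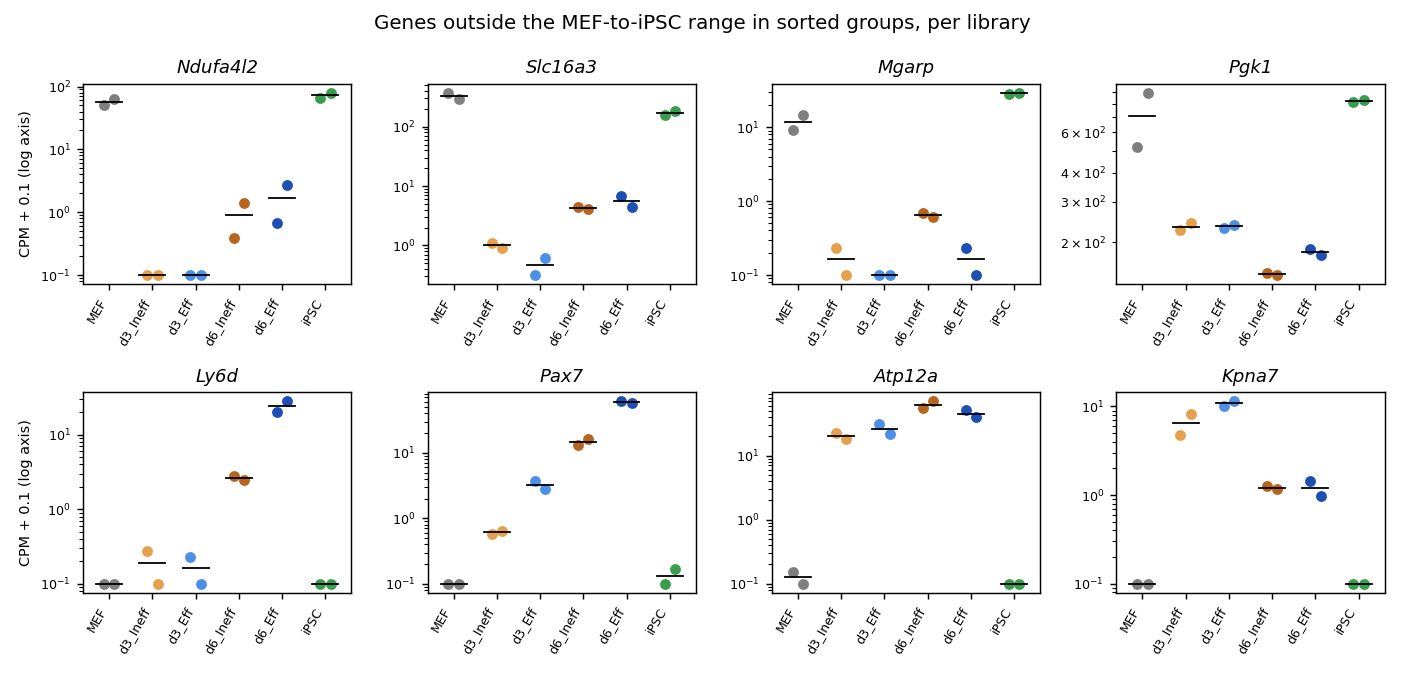
Points show TMM-scaled CPM (log axis, 0.1 added) of 8 genes in each of the 12 libraries, and bars mark the mean of the 2 libraries of a group. Ndufa4l2 and Slc16a3 lie lower in all 8 sorted libraries than in MEF and iPSC, and Ly6d, Pax7 and Atp12a lie higher in d6_Eff than at either end.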

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

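The tests of RNA without a poly-A tail and of transcript length in the MEF pair were chosen after the result was seen. A difference between days was tested as the day 6 Eff against Ineff contrast less the day 3 one, and 225 genes were called, 48 higher and 177 lower. The gates differ between the days, so the difference holds a change of gate besides a change of time. Among the sorting genes and those of the largest differences, the values (log2) were -2.75 for Nt5e, 3.98 for Epcam, -2.23 for Ly6a, -3.43 for Trim9, 1.48 for Nr0b1, -1.66 for Cdkn1c, 8.91 for Esrp1, -3.75 for Atoh8, -8.45 for the endothelial phosphatase gene Ptprb, -5.47 for the Wnt inhibitor gene Dkk3 and -4.55 for the transglutaminase gene Tgm3. Fitted values of 13.92 for Tmem54, 8.93 for B4galnt3, 10.38 for Grb7 and -6.86 for Wdr86 involve groups with 0 or 1 count and move with the prior count. Mesenchymal genes were lower and epithelial ones higher in the day 6 contrast: -2.49 for Vim, -4.37 for Cdh2, -2.68 for Thbs2, -2.30 for Prrx1, -2.65 for Twist1, -2.72 for Ebf1, 3.33 for Cdh1, 5.04 for the keratin gene Krt8 and 2.76 for Sfn. Pluripotency genes gave 5.89 for the RNA-binding protein gene Lin28a, 2.39 for Nanog and -3.40 for Upp1. The remaining values were -2.55 for Vcam1, -2.37 for the chemokine gene Ccl7, -1.78 for Axl, -2.13 for Smad7, -1.90 for Tgfbr2, -1.86 for Ndn, -1.58 for the imprinted gene Nnat and -1.66 for Actg2. Of 33 named and called genes, 4 were called in each refit without 1 library.

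Gene lists also differed between the days by camera. Higher in the day 6 contrast were the epithelial (adjusted p = 2.83e-24, 10 of 40 genes called higher), DNA replication (adjusted p = 1.23e-08), mitosis (adjusted p = 1.68e-06), Myc target (adjusted p = 4.43e-08), pluripotency (adjusted p = 0.00855, 3 higher and 1 lower of 46) and keratinocyte lists (adjusted p = 0.00965, 1 of 10). No gene of the replication, mitosis or Myc target lists was called by edgeR, and 12, 6 and 9 were higher at an unadjusted p under 0.05. Lower were the fibroblast matrix and surface (adjusted p = 2.21e-12, 3 of 40), mesenchymal transcription factor (adjusted p = 2.43e-08, 5 of 41), TGF-beta and YAP (adjusted p = 4.52e-09, 3 of 24), imprinted (adjusted p = 6.29e-07, 5 of 24), smooth muscle (adjusted p = 1.09e-04, 1 of 12) and interferon lists (adjusted p = 0.0456, 0 of 33 by edgeR and 5 at an unadjusted p under 0.05). For inflammation and secreted factors (adjusted p = 0.0155, 2 of 33 lower) the median was -0.90 and the mean 0.04, so the members went both ways. The interferon call was lost without MEF replicate 1 (adjusted p = 0.0567), d3_Ineff replicate 2 (0.0667), d3_Eff replicate 1 (0.170), d6_Ineff replicate 2 (0.126) or d6_Eff replicate 2 (0.0664). The inflammation call was lost without MEF replicate 2 (0.0510), d3_Ineff replicate 1 (0.128), d3_Eff replicate 1 (0.0811), d6_Eff replicate 2 (0.2065) or iPSC replicate 2 (0.0519). With an estimated correlation only the epithelial and replication lists were called (adjusted p = 0.00259 and 0.00828). Lists not called here, such as oxidative phosphorylation and Polycomb and histone modifiers, were called in some refits without 1 library.

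Reads outside genes, which enter the comparisons only in 2 of the alternatives, made up 47.2% of the uniquely placed reads of MEF replicate 2 and 24.1% of d6_Eff replicate 2, against at most 11.7% in the other libraries. The MEF pair also agreed less than the other pairs, with an r of 0.948. Over protein-coding genes without histone genes r was 0.950, against 0.989 to 0.993 in the other pairs. This argues against RNA without a poly-A tail as the whole cause of the lower agreement. It cannot tell whether such RNA made up the reads outside genes, because those reads did not enter r. Identifiers without a symbol took 6.86% of the gene counts of MEF replicate 2 and 2.29% of d6_Eff replicate 2, against at most 1.02% elsewhere. Olfactory receptor exons, silent in these cells, held 0.00253 counts per kb (at most 0.00522) in MEF replicate 2, against 3.146 reads outside genes per kb of genome, which argues against genomic DNA. The log2 ratio of MEF replicate 2 to replicate 1 fell with exon length (Spearman rho -0.501, across genes). This was farther from 0 than in the other pairs (-0.420 in d3_Eff and -0.355 in d3_Ineff come next). A lower yield of long transcripts may therefore be part of the lower agreement. The origin of such a loss and any biological difference between the MEF samples were not tested and stay open. So does RNA without a poly-A tail as a source of the reads outside genes.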

How the results depend on the processing

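Leaving out MEF replicate 2 and d6_Eff replicate 2 together, and the share of reads outside genes as a covariate, were chosen after the data were seen. Changed genes are given here in the order iPSC against MEF, d3_Ineff against MEF, d3_Eff against MEF, the day 3 contrast, the day 6 contrast, d6_Ineff against d3_Ineff, d6_Eff against d3_Eff, iPSC against d6_Eff, and the difference between days. RLE factors (8600, 4884, 5905, 64, 2422, 727, 1515, 4864 and 236) and the replicate number as a block (8321, 4765, 5852, 75, 2321, 649, 1463, 4624 and 214) kept all 9 counts within 1.5 times. Between 15 pairs of groups, the deviations of replicate 1 correlated across genes with r from -0.313 to 0.572, 7 of them above 0.1, so the replicate numbers were not taken to pair the libraries.

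Without genes of overlapping annotation, 7733 genes were tested, and the counts of all comparisons but the day 3 contrast fell with them, to 4092, 2339, 2857, 1199, 420, 739, 2337 and 102. Fits of only the groups compared gave 2138, 3247, 700, 5002, 2574, 2443, 7657 and 1237 from d3_Ineff against MEF onward. For the day 3 contrast, d6_Ineff against d3_Ineff and the difference between days, no filter gave 459, 1362 and 832 (23407 genes tested), and leaving out both libraries with most reads outside genes gave 706, 2693 and 949. DESeq2 gave 445, 1634, 2280 and 833 for these and d6_Eff against d3_Eff, in the order above, and the covariate 425, 3803, 2129, 2356 and 854 from the day 3 contrast on, iPSC against d6_Eff left aside. The cause of these changed counts was not tested. In the main fit all 12 libraries share 1 estimate of spread per gene, so the MEF pair also enters contrasts without MEF. Counts of that pair departed most from sampling noise, with a chi-square per degree of freedom of 380, against 12.3 to 59.5 in the other pairs. The balance of directions moved too: on day 6, 873 higher and 1502 lower genes became 2427 and 2575 in the fit of only these groups (2290 of the 2375 genes among them) and 1714 and 2089 with the covariate. For d6_Ineff against d3_Ineff, 518 and 199 became 1556 and 1018, and 1250 and 879. In fits of only the groups compared, d3_Ineff and d3_Eff against MEF had 853 and 1285, and 1256 and 1991, and iPSC against d6_Eff had more higher than lower genes (4011 and 3646).

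Over the refits without 1 library the counts ranged over 6401 to 8943, 2946 to 6798, 3986 to 7397, 4 to 644, 930 to 4715, 103 to 2607, 657 to 2958, 2834 to 6815 and 20 to 1349. Genes outside the MEF-to-iPSC range numbered 591, 696, 658 and 655 at a 4-fold minimum in d3_Ineff, d3_Eff, d6_Ineff and d6_Eff, and 794 to 1339, 944 to 1522, 937 to 1563 and 871 to 1365 without 1 library. A higher minimum takes fewer genes by construction.

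Of 252 list tests, RLE factors kept 250 on the same side, the block 242, the estimated correlation 167 (85 calls lost) and fry 198 (39 gained, 13 lost). The direction turned for the leukocyte list with fry, which called it higher in d3_Ineff (adjusted p = 0.00394) and d3_Eff (adjusted p = 0.0201) than in MEF, where the median log2 fold change was -3.39 and -2.67 (-3.33 and -2.67 with genes at 0 set to their bound) and camera called neither. The cause was not tested. Of 842 tests of named genes, RLE factors kept 836, DESeq2 831, no filter 825, the block 821, fits of only the groups compared 766 (63 calls lost), and refits without 1 library between 708 (134 lost, without d3_Ineff replicate 2) and 826 (14 lost, without MEF replicate 2). With 9284060 gene counts, MEF replicate 2 set the highest floor, 0.113 CPM over the MEF group.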

Other observations

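The tests in this part were chosen before the values they measure were seen. Ngfr, Tek, Ehf and Igf2, picked after their values were seen, were higher in each of the 4 sorted groups than in MEF and iPSC. Camera did not call the endothelial or neural lists in either day 3 group against MEF. Ngfr, the low-affinity neurotrophin receptor gene of neural crest and stromal cells, was at 0.700 ± 0.397 CPM (SD, n = 2) in MEF, 143 ± 22.7 in d3_Ineff, 171 ± 9.36 in d3_Eff, 184 ± 0.741 in d6_Ineff, 227 ± 29.1 in d6_Eff and 16.4 ± 1.27 in iPSC. Tek, the angiopoietin receptor gene of endothelium, was at 1.91 ± 0.140, 151 ± 4.29, 125.5 ± 18.9, 128 ± 8.25, 71.2 ± 0.572 and 4.61 ± 1.204 CPM in the same order. Ehf, an epithelial ETS factor gene, had 1 count in MEF, 45.6 ± 0.245, 98.0 ± 13.1, 122 ± 16.05 and 92.3 ± 12.4 CPM in the sorted groups and 0.208 ± 0.172 in iPSC. Igf2, an imprinted growth factor gene next to H19, was at 301 ± 125, 2845 ± 313, 3651 ± 145, 4682 ± 594.5, 1230.1 ± 175 and 7.27 ± 2.73 CPM.

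Xist, the RNA of the inactive X chromosome, was at 13.6 to 136 CPM in the 10 libraries of MEF and sorted cells. In iPSC it was at 2.55 and 4.78 CPM. These Xist levels are without TMM scaling. Tsix, which lies opposite Xist, had 26 and 33 counts in iPSC replicates 1 and 2 and none in the other libraries. Counting ignored strand, so reads from sequence shared by Xist and Tsix cannot be told apart. The Y-linked genes Kdm5d, Uty, Ddx3y and Eif2s3y had no counts in any of the 12 libraries. The median log2 fold change of 331 X-linked genes in iPSC against d6_Eff was -0.238 relative to the autosomes, whose own medians lay between -0.0963 and 0.0664. In iPSC against MEF it was -0.214 (348 genes), within the autosomal range of -0.292 to 0.288, and -0.107 without MEF replicate 2, so X-linked genes did not stand apart there. The value against d6_Eff argues against 2 active X chromosomes in iPSC, which would raise X-linked genes. No other explanation of the lower X-linked level was tested.

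The glycolysis and hypoxia lists were lower in the day 3 groups than in MEF and in d6_Eff than in iPSC. A second list of 22 targets of the hypoxia-inducible factor HIF was lower in d3_Eff than in MEF (median log2 fold change -1.35, 17 of 22 genes called lower, camera p = 3.36e-08 at the preset correlation) and higher in iPSC than in d6_Eff (median 1.12, 14 higher and 1 lower, camera p = 5.56e-07), so lower HIF activity may be a candidate explanation. Without MEF replicate 2 the glycolysis list was still called lower in d3_Eff (adjusted p = 2.57e-05; 2.14e-05 to 0.0485 over its alternatives), which argues against loss of long transcripts in that library. A general stress response cannot be told apart from HIF in d3_Eff against MEF. Of 10 ATF4 and NRF2 targets in the hypoxia and glucose stress list, 6 were called lower there and 2 higher. Of its 8 HIF targets, 7 were called lower and 0 higher. The ATF4 and NRF2 targets of the hypoxia and glucose stress list had a median of -1.25 (quartiles -3.09 and 0.33), more than the bound of 1 set for the test above the -4.14 of its HIF targets (quartiles -5.24 and -2.49), but this bound pooled 2 pathways, the quartile ranges overlap, and the ATF4 targets Trib3 and Chac1, picked after their values were seen, fell as far as the HIF targets (-5.30 ± 0.33 and -4.37 ± 0.35). The culture medium differed between MEF, reprogramming cultures and iPSC, was not tested and stays open.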
